A study of Mus musculus with 8 samples.

How the data were processed

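Gene expression was measured by RNA sequencing of polyadenylated RNA from primary epidermal cells of newborn mouse pups. The cells came from pups that were wild type for Dlx3 or carried the Dlx3 knockout, and were transduced in culture with an adenovirus encoding green fluorescent protein (AdGFP, the control virus) or with one encoding the transcription factor Dlx3 (AdDlx3). Libraries were made with the NEBNext Ultra II kit, per the labels' protocols. The design crossed 2 genotypes with 2 viruses, with 2 libraries in each of the 4 groups, 8 in all. Groups and replicate numbers were taken from the sample labels. The labels do not state whether the replicates came from separate pups, litters or cultures, so the p-values measure the spread between these samples, which may be technical.

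Per the submitters' processing notes, which list names without roles, bcl2fastq 2.20.0.422, TopHat2 2.1.1 and Partek (version not given) were used with the mouse build mm10. The annotation, the counting settings and any use of strand are not given in the sources used here. The authors deposited RPKM values (reads per kilobase of gene, scaled to library size) for 26202 genes in the 8 libraries. Of the deposited RPKM values above 0, 1210 were far smaller than any whole read would give, which points to estimated rather than whole reads, so no reads were recovered from them and no count test was run. The deposited sample sheet gives the count of alignments in each library. A second deposited table holds the authors' own comparisons. Its group means are log2 values; that of wild-type AdGFP was the mean of log2(RPKM + 0.1) of the deposited RPKM values, to 3 decimals, in 100% of genes. Per the file headers it also holds p-values and q-values of pairwise contrasts of the 4 groups, and the ratio for each contrast. It further holds a signed fold change, which is the ratio or minus its inverse. The authors' p-values for AdDlx3 in wild-type cells were those of a model of the 4 groups without a batch term: with a batch term, 9.00% of 23012 genes came within 1 percent of the deposited p-value. The authors' table gives no p-value for 3137 genes, whose log2 values are constant. Values from it are named as the authors' wherever they are printed.

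The unit decided the test. RPKM values were changed to log2(RPKM + 0.5), and genes with at least 1 RPKM in at least 2 of the 8 libraries were kept, 12090 of the 26202; 2937 genes were listed at 0 in all libraries. limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, was fitted to all 8 libraries with 4 groups, which left 4 residual degrees of freedom and gave 2.875 prior degrees of freedom. An additive model of genotype and virus, with 5 residual degrees of freedom, gave the effect of each over both levels of the other. Benjamini-Hochberg adjusted p under 0.05 over all genes tested was the threshold for every gene, and every adjusted p of a gene below is from limma. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. Errors of log2 changes are standard errors. Comparisons were the effect of AdDlx3 in wild-type cells, in knockout cells and over both, the effect of genotype under each virus and over both, and the interaction of genotype and virus.

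Before the data were examined, the comparisons, the tests, 30 gene lists and the rule for naming genes were fixed. The rule names Dlx3 in every library first, then for each comparison the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 2 sets of libraries do not overlap, leaving out predicted gene models, which are only counted. From each list up to 4 members with the smallest adjusted p are named. The lists were basal keratinocyte, spinous layer, granular and cornified layer, late cornified envelope, small proline-rich, barrier lipid, differentiation transcription factor, AP-1, Dlx and Msx homeobox, hair follicle, wound keratinocyte, cell cycle, p53 target, inflammation, interferon, Notch, Wnt and Hedgehog, chromatin, mesenchymal and matrix, and heat shock and immediate early genes, with sex-linked genes and markers of fibroblasts, melanocytes, Schwann cells, Merkel and simple epithelia, sebocytes, immune, endothelial, muscle, erythroid and fat cells. Lists with at least 5 measured genes, 25 of the 30, were tested with camera at a preset correlation of 0.01 between genes, which asks whether a list ranks apart from all other genes, with Benjamini-Hochberg adjustment over lists in each comparison. Camera was also run with an estimated correlation, and fry was run on the same fit; fry asks whether the genes of a list move 1 way on balance, or in its mixed form whether they change in either direction, and does not compare them with other genes.

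The deposited sample sheet puts every replicate 1 in batch A and every replicate 2 in batch B, so the replicate numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.379, 0.790, 0.351, 0.529, 0.876 and 0.604 across genes over the 6 pairs of groups. The first principal component held 64.1% of the variance and the second 22.7%. The fit without the batch was fixed beforehand as the main one, and the fit with the replicate number as a block was fixed beforehand as its counterpart, with 3 residual degrees of freedom. A further form, with the block and a term for the response to AdDlx3 in each batch, was chosen after seeing the data. Its error leaves out differences between batches in the response, so its counts for AdDlx3 hold for batch A and batch B only. The counts from all 3 are printed.

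Alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter and a stricter one (a mean of at least 5 RPKM), scaling by the median of ratios and to an equal total per library, a threshold of 0.1, the block, and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. Added after seeing the data were the block with the virus-by-batch term, the block with median-of-ratios scaling, the block with an estimated correlation, and each batch alone. Each batch alone held 4 libraries, with 1 of each group, and left 1 residual degree of freedom. The fitting steps were tested on simulated data of 12090 genes with 50 genes changed at each of 4 sizes. For AdDlx3 in wild-type cells the fit recovered 32% of genes changed by 1 log2 unit, 72% at 2, 94% at 3 and 94% at 4. For AdDlx3 over both genotypes it recovered 56%, 96%, 100% and 98%. For genotype in AdGFP it recovered 28%, 72%, 94% and 94%. The simulated libraries were drawn independently, without batches.

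Positions are from GENCODE vM21 on GRCm38, the assembly that mm10 names, and are 1-based; of 317 symbols looked up, 315 were placed. RPKM values keep the sum of alignments only in part, so no counting interval was made from them. Alignments are counts of aligned positions and not of molecules.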

Results

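RNA of primary mouse epidermal cells was sequenced in 8 libraries, 2 from each combination of Dlx3 genotype (wild type or knockout) and adenovirus (AdGFP or AdDlx3). The deposited counts of alignments were 87121603 and 90990358 in wild-type AdGFP, 84886903 and 91142417 in wild-type AdDlx3, 107719975 and 124857742 in knockout AdGFP, and 73688944 and 96234509 in knockout AdDlx3. Between 11011 and 11594 genes reached 1 RPKM in a library. Krt5, which encodes a keratin of the basal epidermal layer, was the most abundant gene in each AdGFP library, at 1.69% to 2.23% of the RPKM sum. Eef1a1, a translation elongation factor gene, was the most abundant in each AdDlx3 library. Log values of the 2 libraries of a group correlated across genes at 0.980 in wild-type AdGFP, 0.942 in wild-type AdDlx3, 0.960 in knockout AdGFP and 0.947 in knockout AdDlx3.

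Dlx3, a homeobox transcription factor gene (chromosome 11, 95120119 to 95125296, plus strand, GRCm38), was measured at 1.71 and 1.77 RPKM in wild-type AdGFP and at 0.656 and 0.558 RPKM in knockout AdGFP. It reached 237 and 782 RPKM in wild-type AdDlx3 and 402 and 539 RPKM in knockout AdDlx3. Group means were 1.74 ± 0.0418 RPKM in wild-type AdGFP, 0.607 ± 0.0696 in knockout AdGFP, 509 ± 385 in wild-type AdDlx3 and 470 ± 96.7 in knockout AdDlx3 (SD, n = 2 each). Dlx3 rose with AdDlx3 by 7.59 ± 0.50 log2 units in wild-type cells (limma adjusted p = 0.00516) and by 8.72 ± 0.50 in knockout cells (limma adjusted p = 0.00357). The difference of knockout from wild type in AdGFP, -1.02 ± 0.50, did not pass (limma adjusted p = 1 over all genes), although the libraries of both groups did not overlap. In the authors' deposited table Dlx3 was 233-fold higher with AdDlx3 in wild-type cells (q = 0.0352) and 660-fold higher in knockout cells (q = 0.0283), and its fold change of knockout against wild type in AdGFP was -2.61 (q = 1). Which part of the gene the knockout removes is not given in the sources used here, and reads of the virus and of the endogenous gene were not told apart.

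**Figure D1:**
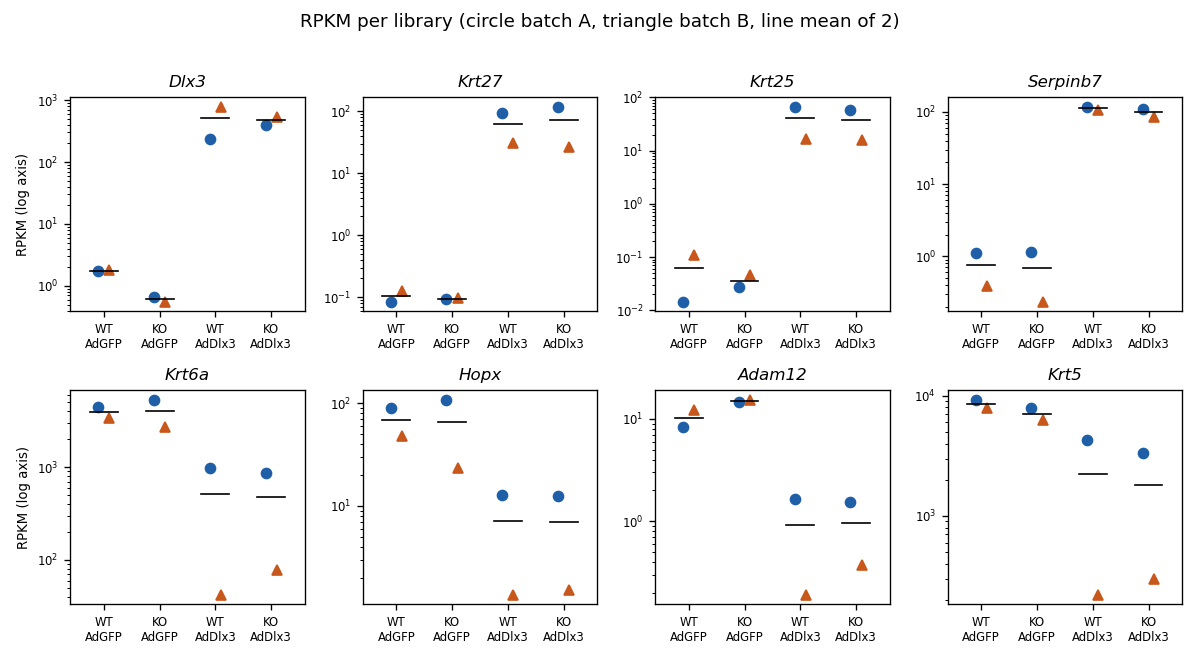
RPKM of Dlx3, Krt27, Krt25, Serpinb7, Krt6a, Hopx, Adam12 and Krt5 in the 8 libraries, on log axes, with 1 panel per gene. Circles are batch A libraries, triangles batch B libraries and lines the mean of the 2 libraries of a group; Dlx3 was between 0.558 and 1.77 RPKM in the AdGFP libraries and between 237 and 782 RPKM in the AdDlx3 libraries.

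The first question was what added Dlx3 did to the transcriptome of these cells over both genotypes, with 4 libraries of each virus. The inner root sheath keratin genes of the hair follicle rose from near absence: Krt27 (chromosome 11, 99345565 to 99351104) by 6.51 ± 0.48 log2 units, Krt25 (chromosome 11, 99315516 to 99322951) by 5.89 ± 0.50 and Krt71 (chromosome 15, 101733949 to 101743109) by 4.55 ± 0.55. Mean Krt27 was 0.106 RPKM in wild-type AdGFP and 61.2 in wild-type AdDlx3, and 0.0952 and 72.0 RPKM in the matching knockout groups. Serpinb7, a serine protease inhibitor gene, rose by 6.51 ± 0.28, the muscle myosin heavy chain gene Myh2 by 5.57 ± 0.38, and the imprinted retrotransposon-derived gene Peg10 by 5.05 ± 0.32. Mlf1 rose by 4.58 ± 0.17 and Cited4, a CBP/p300-interacting factor gene, by 4.33 ± 0.35. Dlx1as rose by 4.66 ± 0.23, but it lies antisense to Dlx1 and use of strand in the counting is not given, so its reads cannot be told from those of its partner. The limma adjusted p of these genes and Dlx3 (8.15 ± 0.38) lay between 4.09e-05 for Mlf1 and 0.00153 for Krt71, and each was higher in all 4 AdDlx3 libraries than in all 4 AdGFP libraries.

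Among the genes with the largest falls over both genotypes, Krt6a, a keratin of activated and wounded epidermis, fell by 4.06 on the log2 scale (SE 1.03, limma adjusted p = 0.0226). Its mean dropped from 3924 to 512 RPKM in wild-type cells and from 4016 to 476 RPKM in knockout cells. These means join unlike batches: wild-type AdDlx3 was at 982 RPKM in batch A and 42.2 in batch B, and knockout AdDlx3 at 876 and 77.0. The response of Krt6a was -2.40 in batch A and -5.72 in batch B. Il33, an epithelial alarmin gene, fell by 3.89 (SE 0.70, adjusted p = 0.00605) and Hopx, a homeodomain gene of differentiating keratinocytes (chromosome 5, 77086988 to 77115121), by 3.52 (SE 0.81, adjusted p = 0.0158). Falls were also seen for Mslnl (-3.52), the tubulin gene Tuba8 (-3.44) and Prnd (-3.43, from -1.98 in batch A and -4.88 in batch B). The calcium-binding protein gene Casq2 (-3.34), the metalloproteinase gene Adam12 (-3.33) and the uroplakin-related gene Upk3bl (-3.31) fell as well, and adjusted p of these 6 genes lay between 0.00138 and 0.0203. In limma 3525 of 12090 genes passed, 2831 up and 694 down, and 1242 of them changed at least 2-fold; 4336 genes had libraries of the 2 viruses that did not overlap, where chance gives 2.86%. With the replicate block 5908 genes passed (4592 up, 1316 down), with the added virus-by-batch term 7452 (5724 up, 1728 down), and all 3525 were among both sets. The error of the fit with the added term leaves out differences of the response between batches, so its count holds for these batches only. With the block and median-of-ratios scaling, a fit added after the data were seen, 4825 passed and more fell than rose (2076 up, 2749 down).

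The median of all genes moved by +0.22 log2 with AdDlx3 over both genotypes, so a gene with no change relative to the rest would show +0.22. Median-of-ratios scaling took this median to -0.06 and left 1169 genes up and 1466 down, against 80.3% up as deposited and 44.4% up after scaling. Without wild-type AdGFP replicate 1 the count fell to 2084 and without wild-type AdGFP replicate 2 to 2279. Leaving out 1 library ended the call of Krt6a 4 times, without either wild-type AdGFP library (adjusted p = 0.0615 and 0.0605), knockout AdGFP replicate 1 (0.0573) or knockout AdDlx3 replicate 2 (0.0555). It ended the call of Upk3bl without either wild-type AdGFP library (0.0533 and 0.0546) or knockout AdGFP replicate 1 (0.0553), and that of Casq2 without wild-type AdGFP replicate 1 (0.0568) or knockout AdGFP replicate 1 (0.0530).

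Hair follicle genes moved in both directions over both genotypes: 6 of 16 measured rose, 5 fell and 5 did not pass (6 and 5 adjusted over the list alone). Besides Krt27, Krt25 and Krt71, Krt28, another inner root sheath keratin gene, rose by 2.39 ± 0.25 (limma adjusted p = 0.000867) and the BMP pseudoreceptor gene Bambi by 1.78 ± 0.17 (adjusted p = 0.000653). Of the Dlx and Msx homeobox genes other than Dlx3, 4 of 6 rose (4 adjusted over the list alone), among them Msx2 by 1.31 ± 0.27 and Dlx1 by 1.90 ± 0.42 (adjusted p = 0.0104 and 0.0140); 2 rose after median-of-ratios scaling. The reads of Dlx1 cannot be told from those of Dlx1as, since use of strand in the counting is not given. Among Notch, Wnt and Hedgehog genes 4 of 21 rose and 7 fell (6 and 7 adjusted over the list alone). Bmp2, which encodes a secreted morphogen, rose by 1.45 ± 0.14 (adjusted p = 0.000623), whereas the receptor gene Notch2 fell by 0.93 (SE 0.13) and the Notch ligand gene Jag1 by 1.33 (SE 0.20).

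Structural genes of the living and cornified epidermis mostly fell or did not pass. Of 15 spinous layer genes 6 fell and 9 did not pass (6 adjusted over the list alone; 12 fell and 1 rose with the replicate block). The Notch target Hes1 fell by 1.48 (SE 0.27, limma adjusted p = 0.00643) and the 14-3-3 sigma gene Sfn by 2.60 (SE 0.59, adjusted p = 0.0144). Of 22 granular and cornified layer genes 10 fell, 3 rose and 9 did not pass (10 and 3 adjusted over the list alone). Within it the cornified envelope genes loricrin (Lor, chromosome 3, 92080271 to 92083142) and trichohyalin (Tchh) rose by 2.75 ± 0.23 and 2.59 ± 0.26 (adjusted p = 0.000381 and 0.000706). Involucrin (Ivl) fell by 1.29 (SE 0.27, adjusted p = 0.0112) and the kallikrein protease gene Klk5 by 2.27 (SE 0.50, adjusted p = 0.0138). Of 15 small proline-rich genes 3 fell and 12 did not pass (2 fell adjusted over the list alone; 11 fell and 1 rose with the block). Sprr2k fell by 1.99 (SE 0.29) and the pseudogene Sprr2j-ps by 2.35 (SE 0.28). Members of this family share sequence, so their values are uncertain. Of 16 late cornified envelope genes only Lce1l passed, up by 0.88 ± 0.18 (adjusted p = 0.00932; 1 up adjusted over the list alone; 4 up and 1 down with the block).

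Of 17 basal keratinocyte genes 2 rose, 2 fell and 13 did not pass; 2 rose and 8 fell adjusted over the list alone, 9 fell and none rose after median-of-ratios scaling, and 2 rose and 11 fell with the block. The plakin gene Dst rose by 0.68 ± 0.12 (limma adjusted p = 0.00555, and 0.0563 after scaling), while the hemidesmosomal integrin gene Itgb4 fell by 0.87 (SE 0.22, adjusted p = 0.0218). The call of Itgb4 was lost without wild-type AdGFP replicate 2 (0.0672), wild-type AdDlx3 replicate 2 (0.0529), knockout AdGFP replicate 2 (0.0609) or knockout AdDlx3 replicate 2 (0.0596). The basal keratin genes did not pass: Krt14 differed by -2.62 ± 0.85 (adjusted p = 0.0523; 0.00449 with the block and 0.0446 after scaling) and Krt5 by -2.97 ± 0.98 (adjusted p = 0.0537; 0.00654 with the block and 0.0477 after scaling). Of 23 barrier lipid genes 1 rose, 3 fell and 19 did not pass (1 rose adjusted over the list alone). After median-of-ratios scaling 1 rose and 5 fell, and with the block 3 rose and 10 fell. The gene that rose was the sphingomyelinase gene Smpd1, by 1.15 ± 0.17 (limma adjusted p = 0.00312).

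Regulators of epidermal differentiation fell more often than they rose. Of 25 differentiation transcription factor genes 10 fell, 1 rose and 14 did not pass (13 fell and 2 rose adjusted over the list alone; 14 fell and 5 rose with the block). Zfp750, a zinc finger activator of late differentiation, fell by 2.99 (SE 0.61, limma adjusted p = 0.00987), the vitamin D receptor gene Vdr by 2.24 (SE 0.47, adjusted p = 0.0110), Prdm1 by 1.34 (SE 0.21, adjusted p = 0.00387) and Cebpb by 0.79 (SE 0.18, adjusted p = 0.0146). Of 10 AP-1 genes 3 fell, 1 rose and 6 did not pass (3 and 2 adjusted over the list alone; 3 fell and none rose after scaling), with Fosl2 down by 1.25 (SE 0.20, adjusted p = 0.00389). Of 16 wound keratinocyte genes 3 fell and 1 rose (3 and 1 adjusted over the list alone; 3 fell and none rose after scaling; 6 fell and 3 rose with the block), among them Krt17, which fell by 2.01 (SE 0.46, adjusted p = 0.0149).

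Of 12 mesenchymal and matrix genes 6 fell, 1 rose and 5 did not pass (6 and 1 adjusted over the list alone; 6 fell and none rose after scaling). The connective tissue growth factor gene Ccn2 fell by 1.98 (SE 0.22, limma adjusted p = 0.00116), the lysyl oxidase gene Lox by 1.09 (SE 0.17) and tenascin C (Tnc) by 2.01 (SE 0.39). Of 24 inflammation genes 8 fell, 3 rose and 13 did not pass (8 and 3 adjusted over the list alone; 9 fell and 1 rose after scaling). The chemokine gene Ccl2 fell by 3.25 (SE 0.55, adjusted p = 0.00481) and Il1a by 1.24 (SE 0.23), whereas the acute phase gene Saa3 rose by 3.69 ± 0.63 (adjusted p = 0.00520). The response of Ccl2 was -1.76 in batch A and -4.74 in batch B. Of 22 interferon genes 6 rose and 16 did not pass (6 adjusted over the list alone; 17 rose and 1 fell with the block). After median-of-ratios scaling 4 rose and 0 fell. The 6 of 22 is near the share of all genes, of which 2831 of 12090 rose. Stat2 rose by 1.40 ± 0.21, Cmpk2 by 1.39 ± 0.21 and the RNA sensor gene Ddx58 by 1.28 ± 0.26 (adjusted p between 0.00317 and 0.00953).

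**Figure D2:**
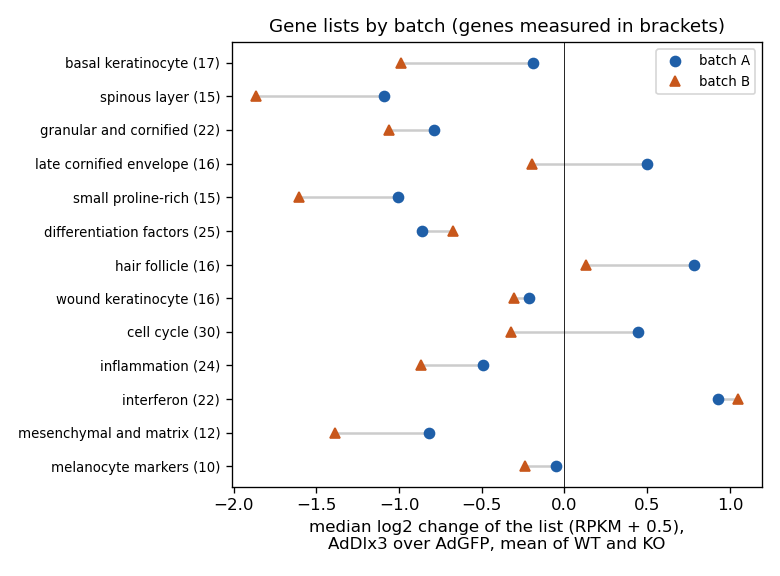
Median log2 change of 13 gene lists with AdDlx3 against AdGFP, as the mean of wild-type and knockout cells, on the scale of RPKM + 0.5. Circles are batch A, triangles batch B, and the number of measured genes stands in brackets; cell cycle genes had medians of 0.45 in batch A and -0.32 in batch B.

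Chromatin genes rose in part: 12 of 43 rose and 31 did not pass (11 adjusted over the list alone; 21 rose with the block), but 3 rose and 1 fell after median-of-ratios scaling. Of all 12090 genes 2831 rose, a share near that of the chromatin list. The genome organiser gene Satb1 rose by 1.41 ± 0.18 (limma adjusted p = 0.00195), the DNA methyltransferase gene Dnmt3a by 0.66 ± 0.11 and the histone methyltransferase gene Ehmt2 by 0.70 ± 0.12 (adjusted p = 0.00410 and 0.00441). Of 25 p53 target genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; 2 rose and 4 fell after scaling; 12 rose and 4 fell with the block). Gdf15 rose by 1.63 ± 0.20 and Bax by 0.79 ± 0.14, and Plk3 fell by 1.77 (SE 0.22). Of 15 heat shock and immediate early genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; 1 rose and 4 fell after scaling), with the chaperone gene Hspa8 up by 1.05 ± 0.23 and Hspb1 down by 1.52 (SE 0.28). Of 30 cell cycle genes the cyclin genes Ccne1 (0.92 ± 0.17) and Ccne2 (0.81 ± 0.17) rose and 28 did not pass (2 adjusted over the list alone; 3 up with the block; adjusted p of Ccne2 = 0.0527 after scaling).

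Markers of other cell types were followed beside these groups. Of 10 melanocyte markers and 5 sex-linked genes none passed with AdDlx3 in limma, and 0 had an unadjusted p under 0.05 (Mitf -0.33, adjusted p = 0.128). After median-of-ratios scaling 2 melanocyte markers fell, and 1 fell with the block. Of 8 fibroblast markers Col1a2 rose by 1.31 ± 0.39 and Col6a3 fell by 0.91 (SE 0.26; adjusted p = 0.0398 and 0.0354; 1 and 1 adjusted over the list alone; 3 and 3 with the block). The call of Col1a2 was lost after median-of-ratios scaling (0.0968) and without wild-type AdGFP replicates 1 and 2 (0.0595 and 0.113), wild-type AdDlx3 replicate 1 (0.0901), knockout AdGFP replicate 2 (0.0981) or knockout AdDlx3 replicate 1 (0.0828). That of Col6a3 was lost without wild-type AdGFP replicates 1 and 2 (0.105 and 0.0598), wild-type AdDlx3 replicate 2 (0.0906), knockout AdGFP replicate 1 (0.0939) or knockout AdDlx3 replicate 2 (0.0901). Of 6 Schwann cell markers Ngfr rose by 1.51 ± 0.23 and 2 fell (2 and 2 adjusted over the list alone). Of 6 Merkel and simple epithelial markers Krt7 fell by 2.60 (SE 0.44; 1 adjusted over the list alone; 2 rose and 1 fell with the block). Of 5 sebocyte markers Plin2 and Fasn fell by 0.70 and 0.71 (2 adjusted over the list alone; 5 with the block). Immune, endothelial and muscle cells had 2, 3 and 2 markers measured: Tnni2 fell by 1.96 (SE 0.43, adjusted p = 0.0130) and Kdr fell by 1.05 (SE 0.25, adjusted p = 0.0171; 0.0586 without wild-type AdGFP replicate 2). Cd74 and Egfl7 rose by 0.81 ± 0.25 and 0.84 ± 0.26 (adjusted p = 0.0413 and 0.0455), but of the 8 fits without a library Cd74 kept its call only without wild-type AdGFP replicate 1 (0.0545 to 0.115 in the others) and Egfl7 only without wild-type AdGFP replicate 2 (0.0574 to 0.124). Lyz2 (-0.07), Eng (0.39) and Mylpf (0.45) did not pass, and erythroid and fat cell lists had 0 measured genes.

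In wild-type cells alone, AdDlx3 raised the hair follicle keratin genes Krt27, Krt25 and Krt71 and lowered Adam12. Krt27 rose by 6.46 ± 0.74 log2 units (limma adjusted p = 0.0171), Serpinb7 by 6.55 ± 0.43 (adjusted p = 0.00516) and Krt25 by 5.90 ± 0.76. Peg10 rose by 5.21 ± 0.48, Myh2 by 5.09 ± 0.51, Dlx1as by 4.78 ± 0.35, Mlf1 by 4.66 ± 0.26, Krt71 by 4.51 ± 0.84 and Cited4 by 4.34 ± 0.54. Adam12 fell by 3.12 (SE 0.59, adjusted p = 0.0475), Fam83a by 2.63 (SE 0.25, adjusted p = 0.0110), and the uroplakin gene Upk1b by 2.38. The growth arrest gene Gadd45g fell by 2.26, the activin subunit gene Inhba by 2.07, the coagulation initiator gene F3 by 2.04, the lipid barrier gene Nipal4 by 2.01 and the kallikrein gene Klk6 by 1.93. Sprr2j-ps fell by 2.53. The ribosomal RNA precursor Rn45s also fell (adjusted p = 0.0139) and was at 1774 and 2130 RPKM in wild-type AdGFP and between 351 and 510 RPKM in the other 6 libraries. In the authors' deposited table Krt27 was 258-fold, Krt25 212-fold, Myh2 146-fold, Serpinb7 145-fold and Mlf1 46.8-fold higher in wild-type AdDlx3.

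In limma 317 genes were called in wild-type cells, 274 up and 43 down, 296 of them changed at least 2-fold; 4 of the 317 were predicted gene models. With the replicate block 2657 passed (2003 up, 654 down). With the added virus-by-batch term, whose error leaves out batch differences of the response, 6090 passed (4606 up, 1484 down). With the block and median-of-ratios scaling more fell than rose (781 up, 1127 down). Median-of-ratios scaling left 155 genes (98 up, 57 down; 63.2% up against 86.4%) and ended the calls of Krt71 and Adam12. Leaving out libraries ended all calls without wild-type AdGFP replicate 1 or 2 (0 genes each) and left 27 without wild-type AdDlx3 replicate 2, 115 without knockout AdGFP replicate 1 or 2, 149 and 170 without knockout AdDlx3 replicates 1 and 2, and 489 without wild-type AdDlx3 replicate 1. The authors' deposited table gave 201 genes at q under 0.05 in this comparison, of which 109 were tested here and 73 called.

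By camera, 12 of the 25 lists ranked below other genes in wild-type cells and none above. They were the lists of basal keratinocyte (adjusted p = 0.000301), spinous layer (7.29e-07), granular and cornified layer (9.11e-05), small proline-rich (3.56e-06), barrier lipid (0.000687), differentiation factor (7.29e-07), AP-1 (0.00953), wound keratinocyte (0.00987), inflammation (0.000119), Notch, Wnt and Hedgehog (0.00104), matrix (5.31e-05) and sebocyte genes (0.000524). None held with an estimated correlation (adjusted p between 0.369 and 0.536 with an estimated correlation), and fry, which asks whether a list moves 1 way on balance, called 0 (2 at an unadjusted p under 0.05, smallest adjusted p 0.112). With the replicate block interferon genes, median +1.02, also passed as higher (adjusted p = 0.00740), but not with the block and an estimated correlation (0.627). Calls were lost for AP-1 genes without wild-type AdDlx3 replicate 1 (adjusted p = 0.192), and for barrier lipid and wound keratinocyte genes without wild-type AdGFP replicate 1 (0.0505 and 0.0515); median-of-ratios scaling ended the wound keratinocyte call (0.226). Single members that passed included Lor (2.49 ± 0.32) and Tchh (2.65 ± 0.39), both up within a list that ranked low, and Cebpb (-1.16 ± 0.18), Bmp2 (1.39 ± 0.21), Satb1 (1.54 ± 0.27) and Ccn2 (-1.82 ± 0.33).

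In knockout cells AdDlx3 gave a response of the same kind. Krt27 rose by 6.56 ± 0.74 log2 units, Serpinb7 by 6.47 ± 0.43, Myh2 by 6.05 ± 0.51, and Krt25 by 5.87 ± 0.76. Peg10 rose by 4.88 ± 0.48, Krt71 by 4.59 ± 0.84, Dlx1as by 4.55 ± 0.35, Mlf1 by 4.50 ± 0.26 and the membrane protein gene Tmem35a by 4.40 ± 0.27 (limma adjusted p between 0.00357 and 0.0348). Adam12 fell by 3.53 (SE 0.59, adjusted p = 0.0290), the epidermal growth factor family gene Epgn by 3.17 (SE 0.53) and the death-associated kinase gene Dapk2 by 3.17 (SE 0.57). The glucose transporter gene Slc2a3 fell by 3.08 (SE 0.67, adjusted p = 0.0496), the receptor gene Ror1 by 3.07 and Shroom1 by 3.07. Upk1b fell by 2.76, the natriuretic peptide gene Nppb by 2.75, the costimulatory receptor gene Cd28 by 2.70 and Serpinb9b by 2.67. In the authors' deposited table Myh2 was 294-fold, Krt27 286-fold, Krt25 227-fold and Serpinb7 150-fold higher in knockout AdDlx3.

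In limma 643 genes were called in knockout cells, 535 up and 108 down, 545 of them changed at least 2-fold; 11 of the 643 were predicted gene models. With the block 2976 passed (2290 up, 686 down). With the added virus-by-batch term, whose error leaves out batch differences of the response, 6083 passed (4639 up, 1444 down). With the block and scaling more fell than rose (1017 up, 1233 down). Scaling left 349 genes (197 up, 152 down; 56.4% up against 83.2%) and ended the call of Slc2a3. Without knockout AdGFP replicate 1 or 2 only Dlx3, Mlf1, Serpinb7 and Tmem35a passed, and without knockout AdDlx3 replicate 1 only Dlx1as, Dlx3, Mlf1 and Tmem35a. Without knockout AdDlx3 replicate 2 the count was 46, and without wild-type AdGFP replicates 1 and 2 it was 115 and 113. The authors' deposited table gave 441 genes at q under 0.05, of which 290 were tested here and 202 called.

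By camera, 10 lists ranked below other genes in knockout cells: basal keratinocyte (adjusted p = 0.000132), spinous layer (5.73e-05), granular and cornified layer (0.00144), small proline-rich (6.63e-05), barrier lipid (0.00174), differentiation factor (0.000200), inflammation (0.000171), matrix (6.38e-05), melanocyte (0.00212) and sebocyte genes (0.00144). None held with an estimated correlation (adjusted p between 0.464 and 0.562 with an estimated correlation), and fry called 0 (3 at an unadjusted p under 0.05, smallest adjusted p 0.102). With the block wound keratinocyte genes (0.0144) also passed as lower and interferon genes (0.0366) as higher, but neither did with the block and an estimated correlation (0.371 and 0.696). The granular and cornified call was lost without knockout AdGFP replicate 1 (0.175) or knockout AdDlx3 replicate 2 (0.0960) and after scaling (0.118), the barrier lipid and differentiation factor calls without knockout AdGFP replicate 1 (0.284 and 0.141), and the melanocyte call without knockout AdDlx3 replicate 2 (0.0853). Members that passed included Lor (3.02 ± 0.32), Tchh (2.54 ± 0.39), Sprr2k (-2.20 ± 0.44), Il1a (-1.56 ± 0.30), Ptgs2 (-1.42 ± 0.30), Jag1 (-1.48 ± 0.29) and Ehmt2 (0.85 ± 0.16).

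By the mixed form of fry, which asks whether the genes of a list change in either direction, 6 lists passed in wild-type and 7 in knockout cells. Hair follicle (adjusted p = 0.000725 and 0.000536), Notch, Wnt and Hedgehog (0.00190 and 0.000536), chromatin (0.0335 and 0.00659), p53 target (0.0335 and 0.0224), granular and cornified (0.0335 and 0.0180) and Schwann cell genes (0.0112 and 0.00693) passed in both genotypes, and matrix genes in knockout cells (0.0304).

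The responses of both genotypes were then set against each other, gene by gene. Of the genes called, 247 rose in both genotypes, where independent lists would share 12.1, and 34 fell in both, against 0.384. Both sets of calls come from 1 fit with the same error for each gene, so independent lists are not a fair reference. By limma 0 genes were called in opposite directions. All 274 genes called up in wild-type cells were also higher in knockout cells, and 534 of the 535 called up in knockout cells were higher in wild-type cells. Of those called down, 40 of 43 and 108 of 108 were also lower in the other genotype. Across the 12090 genes, which are not independent replicates, the 2 responses correlated with r = 0.930 and rho = 0.843. The 2 responses share no library but share both batches: r was 0.887 within batch A and 0.931 within batch B, and 0.753 and 0.697 when the 2 genotypes were taken from different batches.

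**Figure D3:**
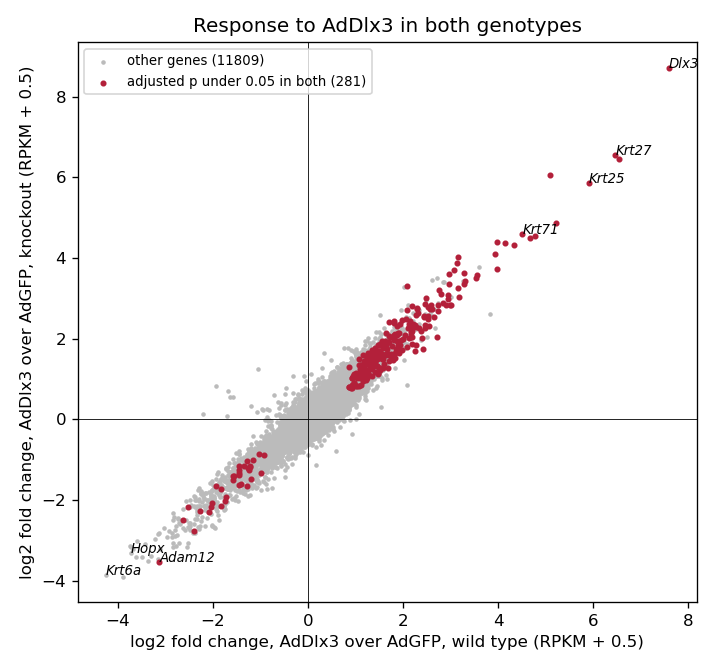
Response to AdDlx3 in wild-type cells (x axis) against that in knockout cells (y axis), in log2 of RPKM + 0.5, for 12090 genes. Red points are the 281 genes past the limma threshold in both genotypes and grey points the 11809 others; the red points lie in the quadrants where both responses have the same sign.

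Whether the response to AdDlx3 differed between genotypes was tested as the interaction. In limma 0 genes were called (40 at an unadjusted p under 0.05), 0 with the block (144) and 0 with the added virus-by-batch term. The counts of 40 and 144 are below the share of 0.05 that chance alone gives, so these fits were conservative here. Dlx3 itself gave 1.13 ± 0.70 (adjusted p = 1). The median standard error of 0.35 log2 limits what this test can detect. By camera, late cornified envelope (adjusted p = 0.0117), differentiation factor (0.0433), AP-1 (0.0433) and Notch, Wnt and Hedgehog genes (0.0433) ranked higher, and melanocyte (0.0117) and sex-linked genes (0.0234) lower, in the knockout response. None held with an estimated correlation (adjusted p between 0.830 and 0.971 with an estimated correlation) and fry called 0 (0 at an unadjusted p under 0.05). Each call was lost in at least 3 of the 8 fits without a library. Differentiation factor and sex-linked genes lost theirs without wild-type AdGFP replicate 1 (0.638 and 0.164), wild-type AdDlx3 replicate 2 (0.715 and 0.298) or knockout AdDlx3 replicate 1 (0.989 and 0.257), and without knockout AdGFP replicate 2 (0.514) and replicate 1 (0.198). AP-1 genes kept theirs only without wild-type AdDlx3 replicate 2 or knockout AdDlx3 replicate 1 (0.0544 to 0.542 in the others), and Notch, Wnt and Hedgehog genes only without wild-type AdGFP replicate 1 or knockout AdDlx3 replicate 2 (0.0725 to 0.874). For late cornified envelope genes these were the fits without wild-type AdGFP replicate 1 (0.149), wild-type AdDlx3 replicate 2 (0.567), knockout AdGFP replicate 1 (0.315) and knockout AdDlx3 replicate 1 (0.106). For melanocyte genes they were those without wild-type AdDlx3 replicate 1 (0.322), knockout AdGFP replicate 1 (0.112) and knockout AdDlx3 replicate 2 (0.542).

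The effect of Dlx3 loss was measured in cells with the control virus, where wild-type Dlx3 was itself low. It was at 1.71 and 1.77 RPKM, just above the filter of 1 RPKM, against 0.656 and 0.558 in the knockout. Melanocyte markers were lower in the knockout: Pmel, which encodes a melanosome fibril protein (chromosome 10, 128704195 to 128720238), differed by -0.69 ± 0.31, Mlana by -0.66 ± 0.21, the pigment transporter gene Slc45a2 by -0.70 ± 0.30 and Dct by -0.48 ± 0.21. All 10 melanocyte markers had a negative difference, with a median of -0.43, and camera ranked the list below other genes (adjusted p = 2.78e-08; adjusted p = 0.784 with an estimated correlation). Genes of the matrix list lay on the other side: the fibronectin gene Fn1 differed by 1.31 ± 0.50, Tnc by 1.19 ± 0.59 and Ccn2 by 0.87 ± 0.33, and the list ranked higher (camera adjusted p = 0.00298; adjusted p = 0.784 with an estimated correlation). None of these single genes passed in limma, with an adjusted p of 1 for each.

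In limma 0 genes were called between genotypes in AdGFP, with 121 at an unadjusted p under 0.05 and a smallest adjusted p of 0.305. With the block 0 were called (456 unadjusted). Both counts are below a share of 0.05 of the 12090 genes, which chance alone gives. The main fit leaves batch differences in its error, so 0 calls do not show that genotype had no effect. With the added virus-by-batch term 5 genes passed: Ifi27l2b was higher in the knockout by 1.64, and Rn45s, Lars2, Mir6236 and Mir6240 differed by -2.32, -2.22, -2.30 and -2.35. These 5 were named after their values were seen. The authors' deposited table gave 30 genes at q under 0.05, of which 0 were tested here because none reached the filter on low values. The libraries of both genotypes did not overlap in 3309 of 12090 genes, where chance gives 33.3%. In data simulated on these values, the fit recovered 28% of genes changed by 1 log2 unit and 72% of those changed by 2. The simulated libraries were independent and had no batches.

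In AdGFP camera also ranked basal keratinocyte genes higher in the knockout (adjusted p = 0.00493) and late cornified envelope (0.00423), differentiation factor (0.00298) and AP-1 genes (0.00298) lower. None held with an estimated correlation (adjusted p between 0.545 and 0.784 with an estimated correlation), and fry called 0 lists (1 at an unadjusted p under 0.05). Cebpb differed by -0.76 ± 0.18, Jund by -0.59 ± 0.20, Lce1e by -0.78 ± 0.33 and Itga6 by 0.52 ± 0.20, none past the threshold. With the block, granular and cornified (0.00769) and small proline-rich genes (4.73e-05) also ranked lower, and fibroblast (0.0241) and Merkel and simple epithelial markers (0.00769) higher; none held with the block and an estimated correlation (0.809, 0.756, 0.756 and 0.623). Without wild-type AdGFP replicate 1 the calls of basal (0.202), differentiation factor (0.202), late cornified envelope (0.106) and matrix genes (0.202) were lost. They were also lost without knockout AdGFP replicate 2 for basal (0.103) and differentiation factor genes (0.498) and without knockout AdGFP replicate 1 for late cornified envelope (0.413) and AP-1 genes (0.0752). The melanocyte call was kept in all 8 fits that left out a library. The log2 differences stayed the same in the fits without an AdDlx3 library, so only those without an AdGFP library test them.

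With the Dlx3 virus in both genotypes, melanocyte markers were also lower in the knockout. Whether the AdGFP and AdDlx3 libraries of 1 genotype and batch came from the same cells is not known here. If they did, this comparison is not independent of that in AdGFP. Pmel differed by -1.06 ± 0.31, Mlana by -0.91 ± 0.21, Dct by -0.84 ± 0.21, Tyrp1, an enzyme gene of melanin synthesis, by -0.84 ± 0.25, Slc45a2 by -0.84 ± 0.30 and the tyrosinase gene Tyr by -0.77 ± 0.26. None passed over all genes, while 8 of the 10 markers passed as lower adjusted over the list alone. The list had a median of -0.81 and ranked below other genes by camera (adjusted p = 4.87e-30, and 0.175 with an estimated correlation). That call was kept in all 8 fits that left out a library. The log2 differences stayed the same in the fits without an AdGFP library, so only those without an AdDlx3 library test them. In limma 0 genes were called in this comparison (45 at an unadjusted p under 0.05, smallest adjusted p 1), 0 with the block (162 unadjusted) and 0 with the added virus-by-batch term. The counts of 45 and 162 are below the share of 0.05 that chance alone gives, so 0 calls do not show that genotype had no effect. The authors' deposited table gave 22 genes at q under 0.05, of which 0 were tested here.

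**Figure D4:**
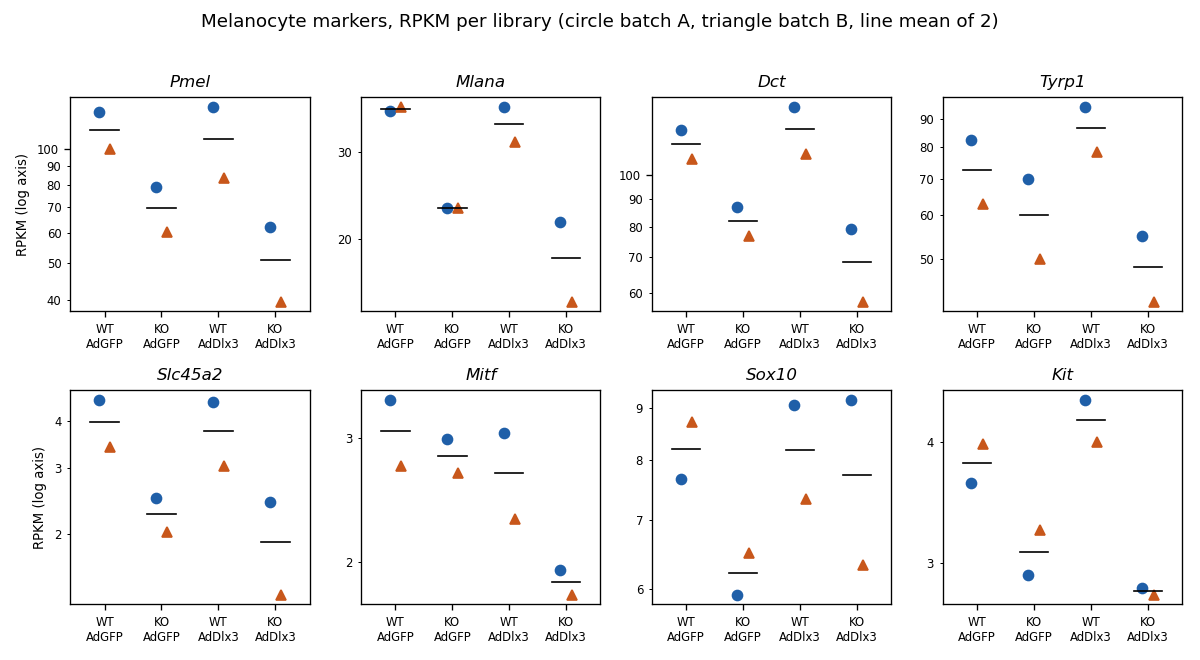
RPKM of the melanocyte markers Pmel, Mlana, Dct, Tyrp1, Slc45a2, Mitf, Sox10 and Kit in the 8 libraries, on log axes, with 1 panel per gene. Circles are batch A, triangles batch B and lines the mean of the 2 libraries of a group. The knockout means of Pmel, Mlana, Dct and Slc45a2 lie below the wild-type means under both viruses. No single marker passed the threshold for genotype in the main limma fit, while these genes passed over both viruses with batch terms.

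Other lists also ranked apart between genotypes under AdDlx3. By camera basal keratinocyte (adjusted p = 0.0248), cell cycle (0.00398), matrix (0.00398) and fibroblast genes (0.0306) were higher in the knockout, and p53 target (0.00398) and sex-linked genes (8.1e-06) lower. None held with an estimated correlation (adjusted p between 0.175 and 0.858 with an estimated correlation), and fry called 0 lists (2 at an unadjusted p under 0.05). The members named by the rule did not pass: the matricellular gene Ccn1 differed by 0.81 ± 0.40, Fn1 by 0.92 ± 0.50, Thy1 by 0.84 ± 0.52, the proapoptotic gene Bbc3 by -0.48 ± 0.21 and the Y-linked genes Uty and Eif2s3y by -0.70 ± 0.27 and -0.64 ± 0.25. Xist, of the same list but named after its values were seen, went the other way: it was at 30.4 and 34.3 RPKM in the 2 batch B knockout libraries and at 12.1 to 16.4 RPKM in the other 6. With the block small proline-rich (0.00879) and inflammation genes (0.0140) also ranked lower and Merkel and simple epithelial markers (0.0130) higher, and none held with the block and an estimated correlation (0.812, 0.812 and 0.488). Without wild-type AdDlx3 replicate 2 the calls of basal (0.119), cell cycle (0.454), matrix (0.820), fibroblast (0.148), p53 target (0.499) and sex-linked genes (0.137) were lost, and without knockout AdDlx3 replicate 1 likewise (0.780, 0.148, 0.420, 0.647, 0.567 and 0.148). Without knockout AdDlx3 replicate 2 those of cell cycle (0.0960) and fibroblast genes (0.0553) were lost, and without wild-type AdDlx3 replicate 1 that of fibroblast genes (0.159).

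Over both viruses, genotype gave 0 limma calls (194 at an unadjusted p under 0.05) and 0 with the block (531 unadjusted). These counts too are below the share of 0.05 that chance alone gives, so these fits were conservative. With the added virus-by-batch term 46 genes passed, 19 up and 27 down in the knockout, a count that was seen before this fit was adopted as an alternative. Whether AdDlx3 moved genotype differences back was asked by counting genes called between genotypes in AdGFP and the other way in the knockout response. There were 0 such genes in limma and 0 with the block, against 0.05 in simulated unchanged groups that share the knockout AdGFP libraries. With the added term there were 3, Lars2, Mir6236 and Mir6240, named after their values were seen. All 3 were higher in the wild-type AdGFP libraries than in all others, and ribosomal RNA carried into those libraries is a candidate explanation. Rn45s, of the same pattern, was at 424 and 355 RPKM in knockout AdGFP and 436 and 419 RPKM in knockout AdDlx3. Wild-type AdGFP held it at 1774 and 2130 RPKM. Across genes the genotype difference in AdGFP and the knockout response correlated at -0.13 with a covariance of -0.0205. The 2 had opposite signs in 56.4% of genes. In 20 simulations of unchanged groups with independent libraries, which leave out the shared batches, these values were -0.50, -0.0797 and 66.6%. In 20 simulations added after the data were seen, in which libraries of 1 batch deviated together as observed, they were 0.07 (0.03 to 0.11), 0.00306 (0.00143 to 0.00520) and 47.7% (47.1% to 48.3%). The observed values lay outside these ranges, on the side of opposite changes. These simulations gave all genes the same correlations, and whether AdDlx3 moved genotype differences back stays open. The knockout AdDlx3 libraries held Dlx3 at 402 and 539 RPKM, far above the 1.71 and 1.77 RPKM of wild-type AdGFP. The added level was thus not the wild-type one.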

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

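The test of the response against batch, and the tests of other cells and of the Dlx3 level, were chosen after the result was seen; the test of library scaling was chosen before. The response to AdDlx3 differed between batch A (replicate 1) and batch B (replicate 2), by a limma term for the difference of the 2 responses. Of 12090 genes 1692 passed (3929 at an unadjusted p under 0.05), 657 with a higher and 1035 with a lower response in batch B. The genes that follow in this part were named after their values were seen. Krt5, the basal keratin gene, fell in both batches and further in batch B: its response differed by -3.58 ± 0.27 log2 units (adjusted p = 0.000311). Its RPKM went from 9244 to 4261 in batch A and from 7903 to 221 in batch B in wild-type cells, and from 7922 to 3330 and from 6223 to 299.8 in knockout cells. In wild-type cells the chitinase-like gene Chil1 went from 0.355 to 16.2 RPKM in batch A and from 0.333 to 0.871 in batch B. The retinoic acid hydroxylase gene Cyp26b1 differed by 1.49 in batch A and by -1.79 in batch B. The growth factor gene Areg was higher by 0.64 in batch A and by 3.93 in batch B, and Trp73, a p63 relative, differed by 0.86 in batch A and by -2.07 in batch B.

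Cell cycle genes had a lower response in batch B in 20 of 30 cases, with a median of 0.45 in batch A and -0.32 in batch B. Basal keratinocyte genes had one in 9 of 17 (-0.19 and -0.99) and hair follicle genes in 9 of 16 (0.78 and 0.13), while 0 of the 22 interferon genes passed (0.93 and 1.05). Of the 1692 genes, 1003 responded in the same direction in both batches, 880 of these more in batch B, and 689 in opposite directions. The count was 867 and 993 without wild-type AdGFP replicates 1 and 2, 566 without wild-type AdDlx3 replicate 2, 743 and 2468 without knockout AdGFP replicates 1 and 2, and 1083 without knockout AdDlx3 replicate 2. Without a filter on low values it was 241. With every library scaled to the same total it was 1567, with 839 higher in batch B, and that split differed from the one of the deposited values.

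For the batch difference 3 explanations were weighed. The tables argue against library scaling as the whole cause, since 1591 genes still differed after median-of-ratios scaling. A larger share of other cells in batch B would raise melanocyte, fibroblast and Schwann cell markers, but the melanocyte markers had a median difference of -0.22 with an SD of 0.23. A higher Dlx3 dose in batch B stays open. In 2 of 2 batches the AdDlx3 library with more Dlx3 had the larger response along the genes that differed, which chance gives with a probability of 0.25. Signed by the direction of the batch difference, the mean responses in batch A were 0.065 and 0.071 in wild-type and knockout cells. Dlx3 was at 237 and 402 RPKM there. In batch B the mean responses were 1.17 and 1.02, with Dlx3 at 782 and 539 RPKM. The gaps within batches were 0.0059 and 0.148, against 1.03 between batches. The 1.03 is large by selection, since these genes were chosen for differing between batches. Dose cannot be told apart from other differences of the batches, and cells with graded AdDlx3 doses in 1 batch would test it.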

How the results depend on the processing

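The fits with the block and the virus-by-batch term, with the block and scaling, with the block and an estimated correlation, and of each batch alone were chosen after seeing the data. A fit of 1 batch rested on 4 libraries and left 1 residual degree of freedom, so its counts carry little weight. With no filter 128 genes passed in wild-type cells and 363 in knockout cells, 1 for genotype in AdGFP (Mir7083), 4 for genotype in AdDlx3 (Gm24195, Krtap4-16, Mir1907 and Mir7061) and 4 for the interaction (Gm24195, Mir1907, Mir7061 and Mir7083), and 34 of the 60 named results kept their call; these 5 genes were named after their values were seen. With the stricter filter 138 passed in wild-type cells, 295 in knockout cells and 2125 over both. Median-of-ratios scaling gave 155 and 349 in wild-type and knockout cells, and a threshold of 0.1 gave 1054 and 1542. The replicate block gave 2657, 2976 and, over both, 5908, and the block with scaling gave 1908 and 2250. The block with the virus-by-batch term gave 6090, 6083 and 7452, with 5 for genotype in AdGFP, 46 for genotype over both viruses and 3 opposite calls. Batch A alone gave 5768 genes for AdDlx3 and 252 for genotype, batch B alone 6688 and 141. Leaving out 1 library gave 0 to 489 genes in wild-type cells, 4 to 733 in knockout cells, 2084 to 3342 over both, and 27 to 58 named results. In wild-type cells the lowest, 0, came without wild-type AdGFP replicate 1 and also without replicate 2. In knockout cells the lowest, 4, came without knockout AdGFP replicate 1 or 2 or knockout AdDlx3 replicate 1 (Dlx3, Mlf1 and Tmem35a passed in all 3), and over both and for named results it came without wild-type AdGFP replicate 1. The lone library of a group was assumed to vary like the other groups. Of the gene lists 41 results passed with the preset correlation of camera, 0 with an estimated correlation, 0 with the block and an estimated correlation, and 51 with the block. Of the 41, 13 lost their call without a filter: all 6 of the interaction, matrix genes for genotype in AdGFP, and for genotype in AdDlx3 basal, cell cycle, p53 target, matrix, fibroblast and sex-linked genes. With the stricter filter 30 kept and 4 lost theirs (differentiation factor, AP-1, Notch, Wnt and Hedgehog, and melanocyte genes for the interaction), and the others were not tested. With median-of-ratios scaling 3 lost theirs: wound keratinocyte genes in wild-type cells, granular and cornified genes in knockout cells, and fibroblast genes for genotype in AdDlx3. With a library left out, 97 list results were newly called, 26 in the opposite direction to the full data; without a library the 2 sides hold unequal batches, so batch differences enter by construction. In 8 cases a list result called in the full data lost its call and changed direction: basal and p53 target genes for genotype in AdDlx3, differentiation factor genes for genotype in AdGFP, and late cornified envelope and differentiation factor genes for the interaction. For the lists that changed direction, newly called or not, the lowest and highest log10 p over the 8 fits, signed by direction, were as follows. For genotype in AdGFP they were -4.19 and 1.99 for spinous, -3.84 and 2.57 for barrier lipid, -10.3 and 0.446 for differentiation factor, -5.99 and 15.4 for cell cycle and -5.61 and 4.65 for interferon genes; for AdDlx3 in knockout cells -5.94 and 2.46 for cell cycle genes. For genotype in AdDlx3 they were -1.26 and 7.19 for basal, -3.93 and 5.87 for spinous, -6.93 and 6.33 for granular and cornified, -4.69 and 7.31 for late cornified envelope, -9.84 and 4.10 for small proline-rich, -3.16 and 2.03 for differentiation factor, -2.98 and 1.64 for hair follicle, -6.29 and 0.399 for p53 target, -6.93 and 3.02 for interferon and -4.54 and 4.54 for heat shock genes. For the interaction they were -2.16 and 4.79 for spinous, -2.82 and 6.44 for granular and cornified, -0.343 and 9.64 for late cornified envelope, -3.96 and 5.65 for small proline-rich, -2.17 and 3.24 for barrier lipid, -0.608 and 8.11 for differentiation factor, -1.74 and 1.55 for hair follicle, -8.16 and 8.96 for cell cycle, -1.78 and 1.67 for p53 target, -5.33 and 3.70 for interferon and -2.02 and 5.35 for heat shock genes. Where a result passed in neither fit, its sign changed in 18 of 5464 comparisons of single genes and 46 of 896 of lists with other settings, and in 329 of 5088 and 97 of 672 with a library left out. Pseudocounts of 0.1 and 1 gave 337 and 311 genes in wild-type cells and 652 and 593 in knockout cells. Apart from the unequal batches, the cause of these changes was not tested.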

Other observations

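The thresholds for genes that came on, the fit with batch terms, the tests of the melanocyte and ribosomal patterns except that of library scaling, the splits for genotype and the comparison with splits that balance the batches were chosen after the results were seen; the 35 splits for AdDlx3 were chosen before. Of the 12090 genes, 8 were below 0.5 RPKM in all 4 AdGFP libraries and at 5 RPKM or more in all 4 AdDlx3 libraries, and 0 went the other way. They were Krt25, Krt27, Krt71, Myh2, Dlx1as, the paired homeobox gene Uncx (4.02 ± 0.21 log2 units, limma adjusted p = 7.92e-05), Fam124a (3.37 ± 0.18) and the cysteine dioxygenase gene Cdo1 (3.21 ± 0.25). Uncx was between 0.00553 and 0.0369 RPKM in the AdGFP libraries and between 5.38 and 10.2 RPKM in the AdDlx3 libraries. Krt25, Krt27 and Krt71 reached 67.0, 92.3 and 25.1 RPKM in the batch A and 16.3, 30.1 and 5.55 RPKM in the batch B library of wild-type AdDlx3.

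With batch terms, genotype over both viruses gave 46 genes in limma, 19 higher and 27 lower in the knockout; those named here were chosen after their values were seen. Myl9 (1.39 ± 0.23), Tagln (1.30 ± 0.17) and Acta2 (1.14 ± 0.15), which encode a myosin light chain, transgelin and an actin, were higher (adjusted p = 0.0483, 0.0230 and 0.0228), as were Fn1 (1.11 ± 0.14), Tnc (0.94 ± 0.13), Thbs1 (0.79 ± 0.13), Ccn2 (0.71 ± 0.10) and Ccn1 (0.67 ± 0.10). The fibroblast marker Thy1 (0.84 ± 0.13) was higher too, and the 8 fibroblast markers had a median of 0.33 with an SD of 0.33. Of the 10 melanocyte markers 4 were lower: Pmel (-0.87 ± 0.09), Mlana (-0.78 ± 0.09), Slc45a2 (-0.77 ± 0.10) and Dct (-0.66 ± 0.09). Saa3 (-1.39 ± 0.15), the pseudokinase gene Trib3 (-0.69 ± 0.09), the transcription factor gene Ddit3 (-0.62 ± 0.10) and the chemokine gene Cxcl10 (-0.60 ± 0.09) were lower too. Ifi27l2b (1.74 ± 0.12) had the smallest adjusted p, 0.000548. The count was 7 without either replicate 1 of AdGFP, 24 without either replicate 2 of AdGFP, 23 without either replicate 1 of AdDlx3 and 65 without either replicate 2 of AdDlx3. It was 31 with median-of-ratios scaling, 19 with equal totals and 0 without a filter. The fit without a batch term called 0 genes (194 at an unadjusted p under 0.05) and that with the block alone 0 (531). Whether the AdGFP and AdDlx3 libraries of 1 genotype and batch came from the same cells is not known here. If they did, the fit with batch terms counts those cells as separate samples, and its errors for genotype are too small.

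Melanocyte markers were lower in the knockout libraries under both viruses: in the model with batch terms all 10 had a negative genotype difference, with a median of -0.60. Other lists were about as one-sided in this model, with smaller medians. All 15 small proline-rich genes (median -0.35) and 24 of 25 differentiation factor genes (-0.17) were negative, and 28 of 30 cell cycle genes positive (0.10). The melanocyte markers were fixed before the data were examined. Dct had the highest mean of the markers over the 8 libraries, at 107 to 134.7 RPKM in the wild-type and 57.8 to 87.0 RPKM in the knockout libraries. The tables argue against a difference of 1 batch, since the medians were -0.64 in batch A and -0.57 in batch B, and against library scaling, which left -0.58. Fewer melanocytes in the knockout cultures may account for it, since the SD of the 10 differences, 0.22, was smaller than their median. A change of pigment genes within melanocytes stays open, as do different pups, since Xist stood apart in the 2 batch B knockout libraries, and counting melanocytes in the cultures would test this.

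Rn45s, Mir6236, Mir6240 and Lars2 were higher in both wild-type AdGFP libraries than in the other 6: Rn45s was at 1774 and 2130 RPKM against 351 to 510. A candidate explanation is ribosomal RNA carried into these 2 libraries, as the 4 differences of knockout from wild type in AdGFP lay within a span of 0.13 log2, between -2.35 and -2.22. The 32 other aminoacyl-tRNA synthetase genes had a median of -0.09 with an SD of 0.15, so Lars2 moved with the ribosomal genes and not with its functional class. A change of ribosomal RNA synthesis in these cells stays open, and was not tested here; an assay of total RNA without polyA selection would test it.

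The 8 libraries make 35 splits into 4 and 4. For AdDlx3 over both genotypes 1 of 35 splits, the real one, gave 3525 genes; the highest other split, which follows the batch, gave 12, and over all 35 splits the share is under 0.05. Of these, 18 put 2 libraries of each batch on each side as the real one does; among them only the real one gave as many genes and the highest other gave 0, but 18 splits are too few for a share under 0.05. For genotype over both viruses limma called 0 genes (194 at an unadjusted p under 0.05), so all 35 of 35 splits give as many by construction and this says nothing about chance. The split by virus gave 4064 and the split by batch 3332, which points to the structure of the samples. With batch terms, 1 of the 8 splits that part each pair of libraries of 1 batch and 1 virus, the real one, gave 46 genes, and the highest other gave 0, but 8 splits are too few for a share under 0.05.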
